A study of Mus musculus with 6 samples.

How the data were processed

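Whole hearts of mouse embryos at embryonic day 16.5 had been dissected, frozen and genotyped, per the labels' protocols, and total RNA was taken with Trizol. From 3 µg of total RNA per sample, biotin-labelled target was hybridised to 1-colour Affymetrix mouse arrays. The embryos were siblings from crosses of heterozygotes on a mixed C57/B6 and 129 S6 background. The labels name 3 biological replicates of each genotype, wild type and FOG-2 R3K5A (called mutant from here on). They do not state the zygosity of the mutants or whether a replicate was 1 heart or several. The p-values therefore measure the spread between these 6 samples.

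The authors' deposited table holds linear probe set intensities that had already been scaled between arrays, as the values show: the array medians of the non-control probe sets lay within 0.121 log2 units. The software and the normalization that made these intensity values are not given in the sources used here, and no detection call was used. The number of arrays limits the precision of every value.

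The table has 45101 probe sets, of which 64 are array controls. The platform annotation gave 1 gene symbol for 34945 of the others, several for 932 and none for 9160. Probe sets with several symbols or none stayed out of the gene-level test. The symbols were looked up in the gene table of assembly GRCm38.p6 by gene identifier, 0 symbols needed updating and 61 probe sets carried a symbol that the table does not hold. No genome build is named for the arrays, so that table was used only for names and for which genes lie near each other.

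Intensities were set to a floor of 1 and log2-transformed. Quantile normalization was reserved for array medians more than 0.2 log2 units apart, a condition these arrays did not meet. Each of 18193 genes was represented by its probe set with the highest mean over the 6 arrays. Genes whose mean did not exceed the median of all non-control probe set means (6.30 log2 units, an intensity of 78.9) were left out, which removed 7080 and kept 11113. Where 1 genotype had a mean at or below that level, the fold is given as a lower bound counted from it.

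The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), and p was adjusted by the Benjamini-Hochberg method over all genes tested, with a gene called at an adjusted p under 0.05. Differences are mutant minus wild type on the log2 scale, with limma's standard error (SE). For single groups the mean and standard deviation (SD) of 3 arrays are given. Gene lists were compared with the other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 30 lists with at least 5 tested genes. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move, on balance, in 1 direction, and its mixed form whether they change in either direction. Fisher's exact test, two-sided, compared the share of changed genes near Zfpm2 with that of all tested genes. Figures were drawn with matplotlib.

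The 34 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Zfpm2, the 15 largest rises and the 15 largest falls among called genes whose genotypes did not overlap (predicted genes and clone names ending in Rik skipped), up to 6 members of each list that passed over the list alone or otherwise the 2 with the smallest p, and Cdkn1a, Nppa, Nppb, Myh7, Myh6 and Gata4. The largest and most informative of these are given with their values, and other genes are said to have been chosen after their values were seen. Alternatives covered the normalization, an offset of 16 before the logarithm, the filter, the probe sets of a gene, the variance model, the threshold, the replicate number as a block, the Xist level as a covariate, sex chromosome genes and genes near Zfpm2 left out, and each array left out.

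The fit was tested on simulated arrays with the means and variances of the 11113 real genes and 200 changed genes in each of 10 runs. It called 50% of genes changed by 0.5 log2 units, 91.9% of those changed by 1 and 98.5% of those changed by 2, and 4.42% of all calls were false. In the same runs, camera called 3 lists in total where nothing had been changed, and called the epicardial list in 10 of 10 runs when its members were raised by 0.5. The simulated genes varied independently, while the correlations estimated in the real lists reached 0.56, for fatty acid oxidation. These runs therefore cannot show how often camera calls lists of correlated genes without a change.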

Results

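Gene expression was measured in whole embryonic hearts of 3 wild-type and 3 FOG-2 R3K5A mutant mice, 1 array per sample. FOG-2, the product of Zfpm2, is a cofactor of GATA transcription factors in the heart, and the R3K5A substitutions are known to remove its binding to the NuRD chromatin remodelling complex. The comparison asks which heart transcripts differ between the genotypes, and cannot by itself tell which of them depend on that binding. Median intensities ran from 77.4 to 84.1 across the arrays. Correlations between arrays over the tested genes were 0.982 to 0.986 within wild type, 0.990 to 0.995 within mutants and 0.972 to 0.990 between genotypes. Wild-type replicate 1 correlated with mutant replicates 1 and 2 at 0.986 and 0.990, against 0.982 and 0.986 with the other wild-type arrays, and 451 genes were called without it against 196 with all arrays. The first principal component held 44.5% of the variance. On it wild-type replicate 1 (-1.08) lay between wild-type replicates 2 and 3 (-21.1 and -11.2) and the mutants (8.55 to 13.1). The mean intensity of the 18S rRNA controls was 969, 429 and 411 on wild-type replicates 1, 2 and 3. In mutants it was 631 to 1051. Whether an RNA or array difference bears on the comparison was not tested. At most 46 of 45101 probe sets had identical values above the floor in any pair of arrays.

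Zfpm2 transcript was higher in mutant hearts, at 10.55 ± 0.03 log2 units (SD, n = 3) against 10.11 ± 0.04 in wild type. The difference was 0.44 (SE 0.06, 1.36-fold, adjusted p = 0.0134). A second Zfpm2 probe set gave 0.58. The allele changes amino acids and need not change the transcript level, so this value does not check the labels. The call was lost without 1 array in 3 of 6 cases (adjusted p = 0.00475 to 0.115 over all alternatives), while the difference stayed between 0.42 and 0.46 in these fits.

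In all, 196 of 11113 genes differed between genotypes, 155 higher and 41 lower in mutant hearts, and 35 of them by at least 2-fold (27 higher, 8 lower), or 32 with genes under the filter level in 1 genotype at their bound. The largest rise was in Spink4, of the Kazal family of serine protease inhibitors, at 9.33 ± 0.12 in mutants against 4.71 ± 0.42 in wild type, a level under the filter. That is at least 8.15-fold (adjusted p = 2.27e-05). Arfgef3 was at least 2.40-fold higher. Nt5e, an ecto-nucleotidase that makes adenosine, rose by 1.69 (SE 0.10, 3.22-fold). Krt18 and Krt8, the paired keratins of simple epithelia, rose 2.91-fold and 2.67-fold. Masp1, a serine protease of the lectin complement pathway, rose 2.84-fold, and Plppr5, also 2.84-fold, and Sdc4, a cell-surface proteoglycan, 2.55-fold. Lrrc2, Sel1l3, Rassf5, Hacd4, Dap and Rassf4 rose by 1.22 to 1.39 log2 units, and Gbp6 was at least 2.22-fold higher. The highest adjusted p among these 15 rises was 0.0497, for Lrrc2. Other probe sets above the filter in both genotypes gave smaller rises for Sdc4 (0.31 log2 units), Nt5e (0.68) and Masp1 (0.17 and 0.81). They gave a similar rise for Lrrc2 (1.33) and larger ones for Plppr5 (1.62), Rassf5 (1.65) and Dap (1.49).

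**Figure D1:**
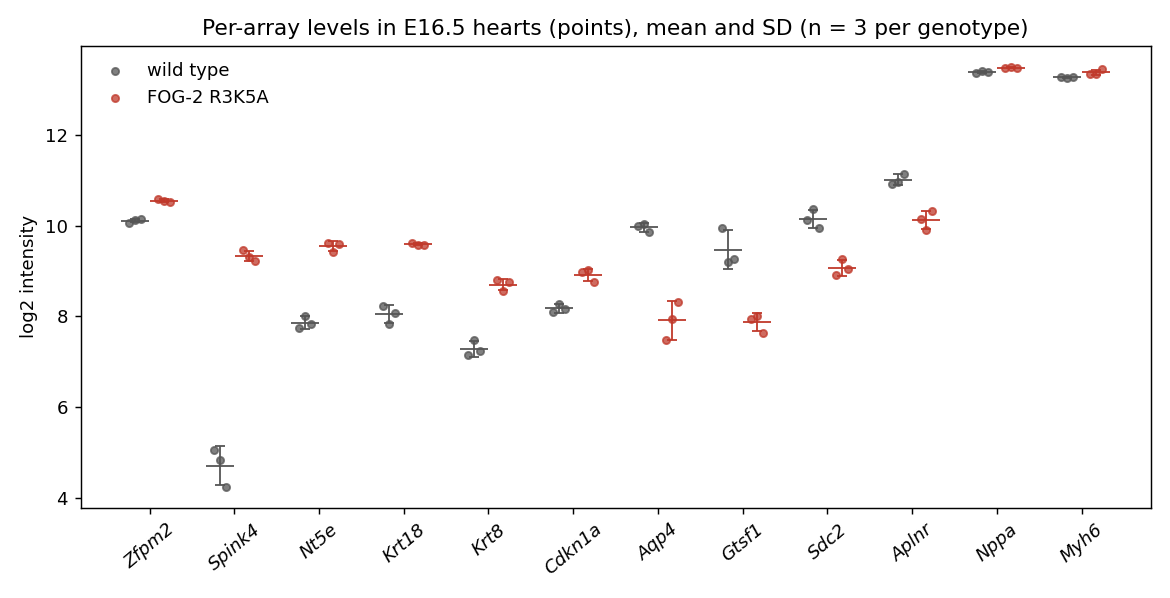
Log2 intensity (vertical axis) of 12 genes on each of 6 arrays, with points for arrays and bars for the mean and SD of 3 arrays per genotype. Spink4 lies at 9.33 in mutants and 4.71 in wild type, while Aqp4 lies at 7.91 and 9.96.

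Aqp4, a water channel, fell most among the called genes, by 2.05 on the log2 scale (SE 0.18, 4.13-fold, adjusted p = 0.00168). Gtsf1, a factor of the piRNA pathway, fell 3.04-fold, Ppp1r1b, a phosphatase inhibitor regulated by dopamine signalling, 2.81-fold and Atpsckmt 2.66-fold. Tcl1b1 was at least 3.03-fold lower. Tnfrsf19 fell 2.45-fold, Sdc2, another cell-surface proteoglycan, 2.11-fold, and Tnni2, the troponin I of fast skeletal muscle, 2.05-fold. Aplnr, the apelin receptor, fell from 11.01 ± 0.12 to 10.13 ± 0.21 (1.84-fold). Slc7a2, Nxpe4, Tmco4 and Grk3 fell by 0.98, 0.93, 0.87 and 0.78 log2 units. Gtsf1 and Tmco4 each had another probe set, under the filter, that did not fall (differences of 0.26 and 0.28). Shd was at least 1.51-fold and Tox at least 1.42-fold lower. The highest adjusted p among these 15 falls was 0.0365, for Shd. Other probe sets above the filter in both genotypes gave smaller falls for Tnfrsf19 (-0.25 log2 units), Sdc2 (-0.35 and -0.80) and Grk3 (-0.58 and -0.65). They gave a similar fall for Aqp4 (-1.97) and a larger one for Aplnr (-0.99).

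At an unadjusted p under 0.05 there were 1636 genes, where 555.6 are expected by chance. The genotypes did not overlap for 2360 genes, 21.2% of those tested against 10% by chance. Both chance values are averages. Genes varied together (the estimated correlation reached 0.56 in a list), so a single comparison can lie far from these averages without a genotype difference. Of the changed genes 93 had another probe set above the filter, and for 11 of these at least 1 such probe set had the opposite sign (Arsb, Atp8a1, Bcl2, Calu, Erlec1, Igfbp5, Itgav, Malat1, Marchf3, Septin6 and Sgms1, named after their values were seen). The number of changed genes was sensitive to single arrays, from 37 without mutant replicate 1 to 451 without wild-type replicate 1. So was the share that was higher, 79.1% with all arrays, 61.4% without wild-type replicate 1 (277 higher, 174 lower) and 88.2% without mutant replicate 3 (45 and 6). It was 43 with the Xist level of each array as a covariate, 119 without the intensity trend and 429 with array quality weights.

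The epicardial list, markers of the outer layer of the heart, was higher in mutants (camera adjusted p = 5.23e-09; adjusted p = 0.361 with an estimated correlation; fry adjusted p = 0.0148). Of 18 members 7 rose over all genes, and adjusted over the list alone 11 were higher and 1, Aldh1a2, was lower. The median difference was 0.54, or 0.49 with Muc16 and Dmkn, under the filter level in wild type, at their bounds. Besides Krt18 and Krt8, Krt19 rose by 0.93 (SE 0.09), Msln, a surface protein of mesothelium, by 0.98 (SE 0.17), Upk3b by 0.50 (SE 0.08), Gpm6a by 0.47 (SE 0.08), and Muc16 was at least 1.39-fold higher. Epicardial transcription factors did not pass, with differences of -0.06 for Wt1, -0.11 for Tbx18, -0.09 for Tcf21 and 0.36 for Bnc1. These 4 genes, Aldh1a2, Muc16 and Dmkn were singled out after their values were seen. On the same arrays the lung secretoglobin Scgb3a2 read 9.03, 4.87 and 11.36 in mutant replicates 1, 2 and 3 and 4.81 to 5.40 in wild type, and its difference did not pass (adjusted p = 0.253).

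**Figure D2:**
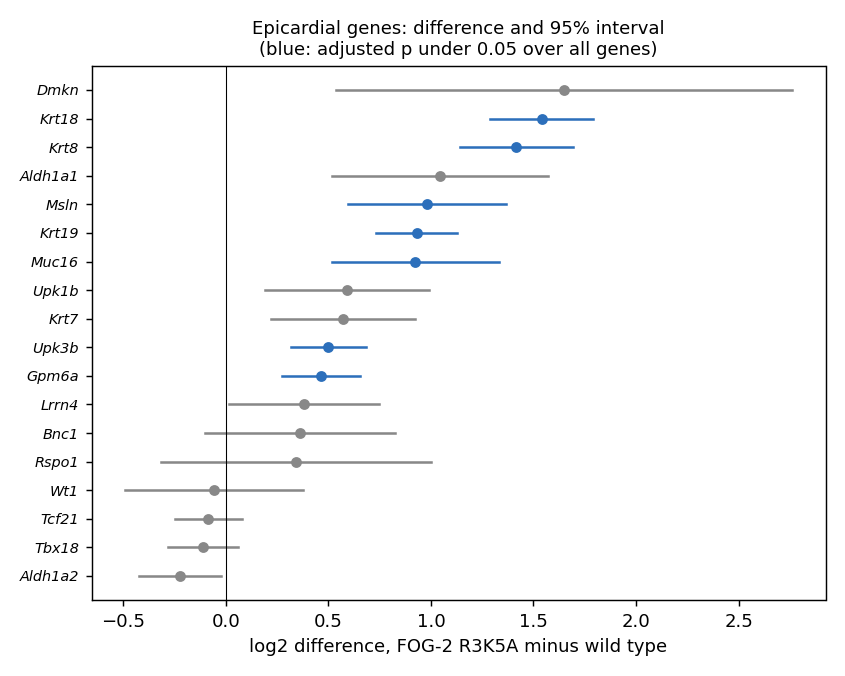
Log2 difference, mutant minus wild type (horizontal axis), of the 18 tested epicardial genes with 95% intervals from limma. Krt18 (1.54) and Krt8 (1.42) lie far from 0, and the intervals of Wt1, Tbx18 and Tcf21 include 0. Muc16 and Dmkn, under the filter level in wild type, are drawn at their fitted differences.

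The fibroblast, valve and matrix list was also higher (camera adjusted p = 0.000179; adjusted p = 0.379 with an estimated correlation). Of 29 members 3 rose, Fbln2 by 0.50, Vcan by 0.50 and Cthrc1 by 0.57, all genes of extracellular matrix, and adjusted over the list alone 5 were higher, Lum and Dcn among them, the latter with another probe set at -0.02. Its 8 collagen genes, looked at after their values were seen, ran from -0.02 to 0.19, and 0 of them passed in either count. Of 19 macrophage and leukocyte genes, 0 passed in either count while 15 had positive differences, and camera called the list higher (adjusted p = 0.0194; adjusted p = 0.379 with an estimated correlation). F13a1 had 0.51 and Fcgr3 0.60. Of 23 hypoxia targets 0 passed and 17 were positive (camera adjusted p = 0.0194; adjusted p = 0.563 with an estimated correlation), with Bnip3 at 0.21 and P4ha2 at 0.36.

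Cell cycle lists were lower by small amounts. Of 37 G2/M and mitosis genes 34 had negative differences, with a median of -0.09 (camera adjusted p = 0.0043; adjusted p = 0.563 with an estimated correlation), and of 38 G1/S and DNA replication genes 33 did, with a median of -0.07 (camera adjusted p = 0.0249; adjusted p = 0.691 with an estimated correlation). In both lists 0 genes passed over all genes or over the list alone. Both calls ended with the mean over the probe sets of a gene and without wild-type replicate 1, and that of G1/S also without mutant replicate 3. Bub1b had -0.23, Kif11 -0.17, Ccne1 -0.36 and Orc1 -0.35. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose by 0.74 (SE 0.10, 1.67-fold, adjusted p = 0.0120). The lists that hold it did not pass, with camera adjusted p = 0.208 for the CDK inhibitors and 0.0628 for the p53 targets, where Plk2 had 0.38. Among ATF4 and unfolded protein response genes (camera adjusted p = 0.0628), Nupr1 rose by 1.13, with its other probe set at 0.31, and Aldh1l2 fell by 0.47.

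Of 27 cardiac transcription factors 21 had negative differences, and the list was lower (camera adjusted p = 0.03; adjusted p = 0.563 with an estimated correlation). Tbx20 fell by 0.38 and Zfpm2 rose. Gata4 had -0.31 (adjusted p = 0.520), Gata6 -0.50 and Zfpm1, which encodes FOG-1, 0.50, and the list of GATA and FOG factors did not pass by camera (adjusted p = 0.586), but its members moved both ways, with Zfpm2 and Zfpm1 higher and Gata6 lower over the list alone (mixed fry adjusted p = 0.000543). The subunits of NuRD did not pass either (0.577, with Chd3 at 0.24 and Chd4 at -0.25, while the other two Chd4 probe sets above the filter had 0.21 and 0.12). Sarcomere and calcium handling genes did not pass (camera adjusted p = 0.577), with Myh6 at 0.11, Myh7 at 0.04 and Mb at -0.30. In the atrial and fetal stress program (adjusted p = 0.0534, 4 members higher over the list alone) Nppa had 0.10 (adjusted p = 0.174), Nppb 0.48 (adjusted p = 0.145) and Myl7 0.14. The genotype means of Nppa, Myh6 and Myh7 were 13.3 to 13.5 log2 units, as bright as the brightest array controls (up to 13.5 in wild type). Whether differences were compressed at that brightness was not tested, so their small size does not show unchanged transcripts. The potassium channel genes Kcnj3 and Kcne1 rose by 0.69 and 0.77, while the conduction and ion channel list did not pass (camera adjusted p = 0.932), with 3 members higher and 3 lower over the list alone. Kcnip2, a channel subunit of the transient outward current, was at least 4.83-fold lower in the means, with a wild-type SD of 1.16, and did not pass (adjusted p = 0.0510). Compact and trabecular myocardium did not pass by camera (adjusted p = 0.577), but members moved both ways, with 1 higher and 5 lower over the list alone and the smallest mixed fry adjusted p of all lists (0.00043). The lower ones were Tbx20, given above, Prdm16 at -0.40, Mycn at -0.39, Cited1 at -0.41 and Hey2 at -0.25.

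Fatty acid oxidation genes were lower as a list (camera adjusted p = 0.0249; adjusted p = 0.696 with an estimated correlation), with 21 of 25 negative and 0 called, as in Acaa2 at -0.15 and Ppargc1a at -0.21. That call ended in 7 of 14 alternatives: median centring, the Xist covariate, an estimated correlation, fry, and without wild-type replicate 2 or 3 or mutant replicate 2. Glycolysis (adjusted p = 0.819) and oxidative phosphorylation (0.078) did not pass, though the latter was called in 4 of 14 alternatives (adjusted p = 0.000493 to 0.972). Endothelial and coronary vessel genes did not pass as a list (0.184; 4 members higher and 1 lower over the list alone), though Vwf rose by 0.92 beside the fall of Aplnr, and Plvap had 0.50. Growth factors of the myocardium (adjusted p = 0.986) held a fall of Fgf9 by 0.59 and a rise of Igfbp5 by 0.25, Notch, BMP and TGF-beta targets (0.078) a rise of Id4 by 0.59, and immediate early genes (0.17) a rise of Fosl2 by 0.62. Imprinted growth genes had an adjusted p of 0.078, interferon response genes 0.586 and smooth muscle and mural genes 0.722.

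Among markers of other tissues, skeletal muscle genes had an adjusted p of 0.0613, with falls of Tnni2 and of Casq1 by 0.41. Erythroid genes had 0.184, lung and airway genes 0.184 and neural genes 0.29, where Uchl1 had 0.61. Thymus, liver and fat lists had too few tested genes for a test, with Cd8a at -0.34, Ttr at 0.03 and Ebf2 at 6.75 ± 0.53 in wild type and 5.94 ± 0.33 in mutants, a level under the filter, with genotypes that overlapped and no call over all genes. Of 30 lists tested camera called 8, 4 higher and 4 lower, and 0 with an estimated correlation. Fry called 1 list, and 14 in its mixed form. Median, mean and test differed in sign in 9 lists, none of them called: GATA and FOG factors, sarcomere, compact myocardium, conduction, smooth muscle, neural, glycolysis, immediate early and interferon genes.

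**Figure D3:**
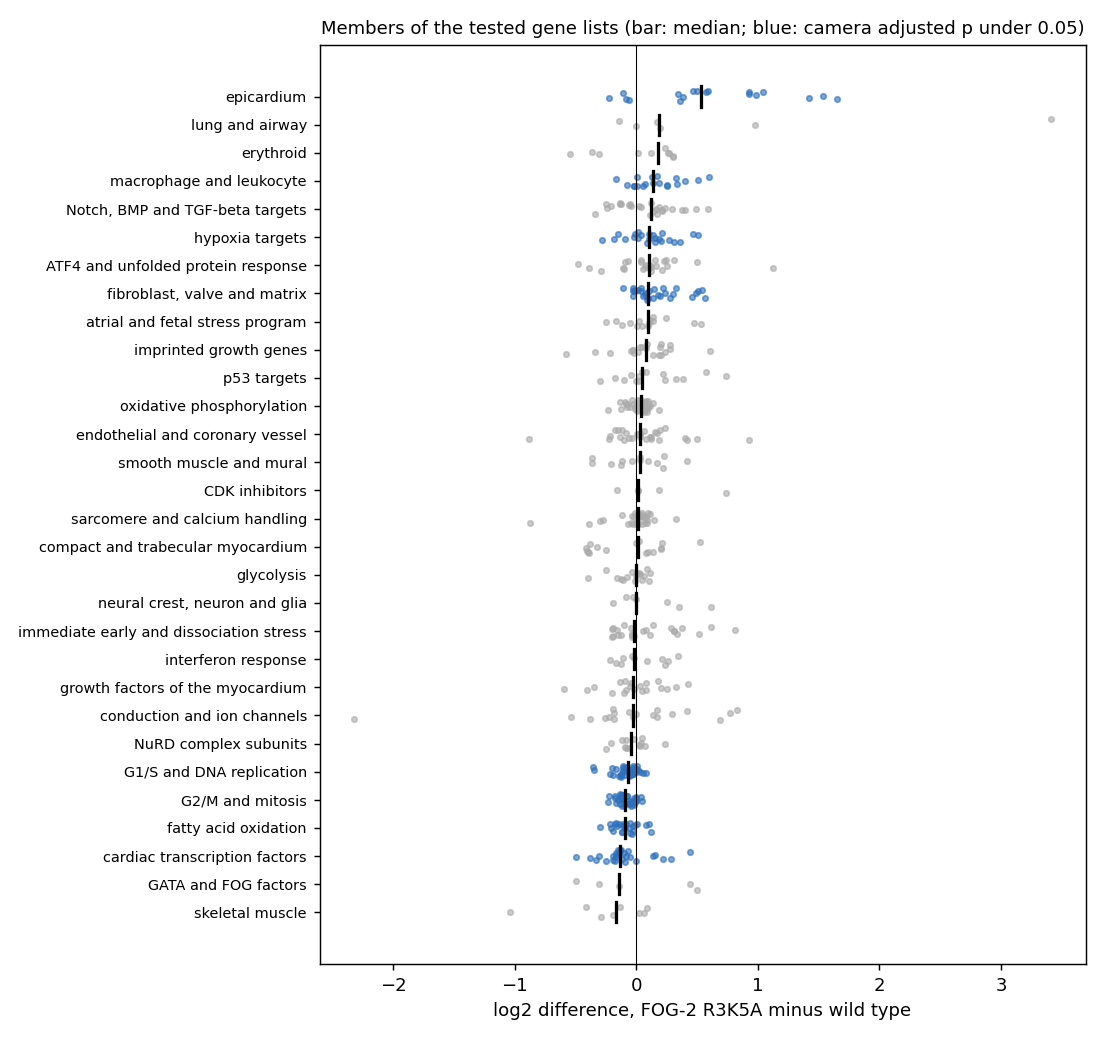
Log2 difference, mutant minus wild type (horizontal axis), of each tested member (points) of 30 gene lists, with bars at the list median and lists called by camera in blue. The epicardial median lies at 0.54, and the G2/M median at -0.09. Members under the filter level in 1 genotype are drawn at their fitted differences.

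Because the background mixes strains, the place of changed genes relative to Zfpm2 on chromosome 15 was compared with that of all genes. Within 20 Mb of Zfpm2, by the order of genes in GRCm38.p6, lay 5 of 196 changed genes (2.55%) against 86 of 11113 tested (0.774%), an odds ratio of 3.50 (Fisher's exact p = 0.0179). They were Zfpm2, Cthrc1, Sdc2, Atpsckmt and Dap, all within 10 Mb (odds ratio 7.30, exact p = 0.00101). Cthrc1 and Atpsckmt were each read by only 1 probe set above the filter. Within 40 Mb the odds ratio was 1.92 (exact p = 0.0808), and without wild-type replicate 1 it was 2.11 (exact p = 0.0878). In settings without Zfpm2 itself, chosen after seeing the data, it was 2.80 for changed genes (exact p = 0.0622), 2.41 for genes at an unadjusted p under 0.01 (exact p = 0.0163) and 12.6 for genes changed at least 2-fold, of which 3 of 35 lay near (exact p = 0.00237).

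The sex of the embryos is not in the labels. Xist, expressed from the inactive X chromosome, read 10.82 to 12.12 log2 units on the 6 arrays, and the Y-linked Eif2s3y 8.77 to 10.30, both above the filter on 6 of 6 arrays. Xist was 11.91 ± 0.29 in wild type and 11.48 ± 0.58 in mutants (SD, n = 3), a difference of -0.43 (adjusted p = 0.457). The mean of Eif2s3y, Kdm5d and Uty was 7.78 ± 0.68 and 8.20 ± 0.73. Genes on the X chromosome made up 5.1% of the changed genes (10) and 3.29% of those tested (366).

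**Figure D4:**
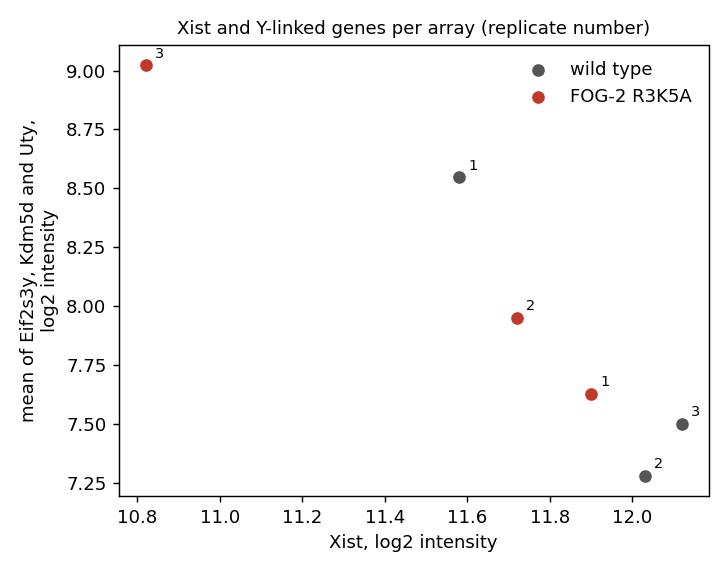
Xist (horizontal axis) against the mean of 3 Y-linked genes (vertical axis), both in log2 intensity, for each array with its replicate number. Mutant replicate 3 had the lowest Xist (10.82) and the highest Y-linked mean (9.02). Wild-type replicate 3 had the highest Xist (12.12, with 7.50), and wild-type replicate 2 the lowest Y-linked mean (7.28, with Xist at 12.03).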

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

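Tests in this part were chosen after the results were seen, except the test of every probe set, the test for linkage to Zfpm2, the group difference of the sex-linked genes (its limma intervals were chosen later), the Xist covariate and the splits of the gene count.

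Probe sets without a single gene symbol stayed out of the gene-level comparison, and 12 of them changed between genotypes, 5 higher and 7 lower. The largest difference was a fall from 7.89 to 4.96 log2 units, at least 3.01-fold (adjusted p = 0.0499 by limma), and the largest rise was 1.13.

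Changed genes were more frequent near Zfpm2 than elsewhere. Flanking DNA of 1 parental strain, carried with the knock-in allele, is a candidate explanation, and the planned test went with it (exact p = 0.0179), while the rest of chromosome 15 had an odds ratio of 1.15. Without Zfpm2 itself p was 0.0622 for changed genes, 0.0163 for genes at an unadjusted p under 0.01 and 0.00237 for genes changed at least 2-fold, all by the exact test in settings chosen after seeing the data. Direct effects of the mutation on these genes stay open. A variant under a single probe set is argued against for 3 genes, Dap, Sdc2 and Zfpm2. For these, every probe set above the filter moved the same way at an unadjusted p under 0.05. Variants under several probe sets of a gene stay open, and the falls of the 3 Sdc2 probe sets were uneven (-1.08, -0.80 and -0.35). For the other 2 genes, Atpsckmt and Cthrc1, a variant cannot be told apart from a changed transcript level, because only 1 probe set was above the filter.

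Xist and Y-linked genes were read on the same arrays. They varied in opposite directions over the 6 arrays (Pearson r = -0.940, exact permutation p = 0.00417; Spearman rho = -0.943, exact permutation p = 0.0167; the only relation computed), and r was -0.984 without the 2 arrays farthest from the median. Background of the Y-linked probe sets alone is argued against by that relation and by a range of 1.74 log2 units. Pooling of hearts of both sexes may account for 2 arrays, wild-type replicate 1 and mutant replicate 3, where the Y-linked mean lay over 1 log2 unit above the lowest array with Xist still high. Whether the other arrays were mixed stays open, as does carry-over of RNA between samples, and a sex difference between genotypes cannot be told apart from the mutation at a Xist difference of -0.43. By limma (SE 0.25) the 95% interval of Xist just stayed within the 1 log2 unit named in advance. Those of Eif2s3y (0.42, -0.34 to 1.19), Kdm5d (0.39, -0.59 to 1.38) and Uty (0.46, -0.47 to 1.38) passed it, which keeps the question open, and 43 genes were called beside the Xist covariate.

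The epicardial list was higher in mutant hearts. An even gain in epicardial cells as the whole cause is argued against by 4 members (Wt1, Tbx18, Tcf21 and Aldh1a2) whose 95% intervals lay wholly below the list median and 4 (Msln, Krt19, Krt8 and Krt18) wholly above it, although other cell types also express some of these. If a lower share of cardiomyocytes raised all other cell types evenly, endothelial genes would rise alike. The epicardial mean rose by 0.57 more than the endothelial mean (two-sample SE 0.06, exact permutation p = 0.1, the smallest that 3 against 3 allows). That bears only on an even shift. An uneven one stays open, and endothelial members themselves moved both ways, 4 higher and 1 lower over the list alone. Carried-over lung as the whole cause is argued against by only 1 array, mutant replicate 2. There Sftpc (5.80) and Scgb3a2 (4.87) were not above the wild-type range, under the filter level, and the epicardial median was still 0.44. On replicate 1 Sftpc was 6.17 but Scgb3a2 9.03, so carried-over airway stays open there. The epicardial median was higher, at 0.66 and 0.60, on replicates 1 and 3, where Scgb3a2 read 9.03 and 11.36. Changed expression of keratin and mesothelial genes in mutant hearts, carried-over pericardium and a partial gain of epicardial cells stay open; Krt8, Krt18, Krt80 and Gtsf1 also lie on chromosome 15, more than 40 Mb from Zfpm2.

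With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. The real split called 196 genes and the highest other 0, so 1 split gave as many. The other splits all mix the genotypes, so a genotype difference would widen their spread and lower their counts. They therefore cannot show how many genes would be called without a genotype difference. For gene lists the real split called 8 and the highest other 14, and 3 splits called as many. The split with 14 set wild-type replicates 1 and 3 and mutant replicate 2 against the rest, and why it called more was not tested.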

How the results depend on the processing

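The number of changed genes was 196, and it was 81 without the filter, 126 with the stricter filter, 125 with the mean over probe sets, 119 without the intensity trend, 429 with array weights, 43 with the Xist covariate, 369 at an adjusted p under 0.10 and 115 at 1.5-fold or more. Other settings gave 180 to 234. Left out in turn, wild-type replicates 1, 2 and 3 gave 451, 92 and 61 and mutant replicates 1, 2 and 3 gave 37, 84 and 51. The drop has fewer arrays as part of its construction, while the cause of the rise to 451 was not tested, nor was that of the shifts under the other settings, apart from the changed thresholds. The replicate block gave 234 genes and the same 8 lists. Correlations of deviations between genotypes were -0.058, 0.13 and 0.41 for arrays sharing replicate number 1, 2 and 3. For arrays with unlike numbers they were -0.32 to 0.25. Only 1 of 3 wild-type arrays correlated best with its own number. Whether the numbers mark pairs, above all at replicate 3, stays open, because 3 pairs cannot decide it.

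Camera called 8 lists, 0 with an estimated correlation and 1 with fry, and 5 to 13 with an array left out. The epicardial and fibroblast lists were called in 6 of 6 such fits, G2/M in 5 (not without wild-type replicate 1), fatty acid oxidation in 3 (not without wild-type replicate 2 or 3 or mutant replicate 2) and the other 4 in 4: G1/S and hypoxia were lost without wild-type replicate 1 or mutant replicate 3, macrophage and cardiac transcription factors without wild-type replicate 2 or mutant replicate 3. With all arrays, the mean over probe sets ended the calls of G1/S, G2/M and cardiac transcription factors and left 1 list lower, the Xist covariate those of cardiac transcription factors, macrophage and fatty acid oxidation, and median centring that of fatty acid oxidation. Over all alternatives the adjusted p ran from 3.02e-11 to 0.361 for the epicardial list, 1.28e-06 to 0.379 for fibroblast, 0.00454 to 0.379 for macrophage, 0.000378 to 0.563 for hypoxia and for G2/M, 0.000241 to 0.822 for G1/S, 3.93e-05 to 0.696 for fatty acid oxidation and 0.00555 to 0.563 for cardiac transcription factors. Of the 22 other lists 12 were called in some alternative, 5 of them with all arrays: atrial in 5 of 14 alternatives, skeletal muscle and oxidative phosphorylation in 4, p53 targets in 3 and immediate early genes in 2. Zfpm2 stayed higher, at 0.42 to 0.46 with an array left out, and did not pass with the Xist covariate (0.47). The odds ratio near Zfpm2 was 1.92 within 40 Mb, 1.62 for the chromosome and 2.80 without Zfpm2 (none past 0.05), 2.41 and 12.6 without Zfpm2 at the 2 other thresholds, and 2.11 to 11.7 with an array left out (not past 0.05 without wild-type replicate 1). Of 49 called named genes apart from Zfpm2, 0 turned their sign in the alternatives that tested them (42 genes with the mean over probe sets, 32 with the stricter filter), though the other probe set of Igfbp5 had -0.07. Of the 49, 47 stayed called with quantile normalization, 21 with the Xist covariate and 20 without mutant replicate 1 or 3. Signal over background limits Spink4, Arfgef3, Tcl1b1, Gbp6, Shd, Tox, Kcnip2 and Muc16, given as bounds.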

Other observations

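Genes in this part were chosen after their values were seen. Apela, which encodes a ligand of the apelin receptor, rose by 1.16 log2 units (SE 0.15) in mutant hearts while the receptor gene Aplnr fell by 0.88. Both monoamine oxidase genes rose, Maoa by 0.91 (SE 0.12) and Maob by 0.67 (SE 0.12). Grk5, a kinase that acts on G protein-coupled receptors, rose by 0.76, and Grk3, another, fell by 0.78. Clu, which encodes a secreted chaperone, rose by 0.81.

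Kcnip2 read 7.24 on wild-type replicate 1 and 9.17 and 9.31 on the other two wild-type arrays, against 5.82 to 6.62 in mutants. Sftpc, a surfactant gene of lung, read 9.43 on mutant replicate 3 and 5.80 to 6.53 on the other arrays.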
